A study of Mus musculus with 26 samples.

How the data were processed

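The series holds 26 Affymetrix MOE430A arrays of mouse dorsolateral prostate. Per the labels' protocols, about 1000 epithelial cells were cut from frozen tissue of mice aged 8 to 16 months by laser capture microdissection. This technique lifts chosen cells off a section under the microscope. Areas were chosen by their histology, and their RNA was linearly amplified, labelled with biotin and hybridised. The labels name the histological stage and a genotype code for each array. Each array carries a different number in its title, but no label says outright that each came from a separate mouse, so the p-values below measure the spread between these samples. If some areas shared a mouse, those p-values are too small.

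The deposited table holds 22690 probe sets in 26 columns, all of which were matched to a sample. Per the submitters' processing notes, MAS5 and RMA were used; the notes read here give neither their role nor their version. The deposited values are linear ratios: in 22690 of 22690 probe sets the median over the 4 Normal arrays was 1 within 0.001, so each probe set had been divided by its own median in normal tissue. The scale, the division and the centring were worked out from the values. Levels before the division, signal over background and detection calls are unknown, and a probe set near background cannot be recognised. The lowest ratio was 0.01. It occurred 6 times, always in the probe set of Pbsn, so the falls of Pbsn are lower limits in those arrays.

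Ratios were taken to log2 with no pseudocount. Dividing a probe set by one constant shifts its log2 values equally in every array, which leaves differences between groups unchanged. Array medians ranged from -0.08 to 0.01 on the log2 scale, so no further normalization was applied. The plan made before the data were examined had foreseen either log2 values or MAS5 levels with a pseudocount of 16, and neither applied. Gene names came from a table pairing probe sets with the platform's annotation. Of the probe sets, 64 were Affymetrix controls, 20380 had 1 gene symbol, 691 had several and 1555 had none. The RefSeq gene table of GRCm38.p6 held 20351 of the named identifiers and changed 0 symbols. Only probe sets with 1 symbol were tested, and each gene was represented by 1 probe set. Probe sets with the plain suffix were preferred to those with suffixes for shared or cross-hybridising probes, then the lowest identifier. This gave 12393 genes, of which 4956 had several probe sets. Nkx3-1, Pten and Ar had 0 probe sets with a name of their own in that table and were not analysed here, so the mutant genes themselves could not be used to check the labels.

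Groups were fitted with limma 3.58.1 in R 4.3.3: a linear model with a mean for each of the 5 stages over all 26 arrays, followed by empirical Bayes moderation. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 12393 genes, with a threshold of 0.05. All adjusted p-values for genes in the text come from limma. Differences are given as log2 differences ± SE of the fit, and group values as means ± SD of log2 ratios. A moderated F test asked which genes differed among the stages. Genotype within Dysplasia-LGPIN was tested in a fit that divided this stage into genotype N and the other genotypes. On simulated data built on the 12393 genes with 100 genes changed by 1 log2 unit and 100 by 2, the fit recovered 86% and 100% for Dysplasia-LGPIN minus Normal. It recovered 91% and 98% for HGPIN-Cancer minus Dysplasia-LGPIN, and 86% and 97% for AI-HGPIN minus HGPIN-Cancer. The values were 85% and 100% for AI-Cancer-MET minus AI-HGPIN, 86% and 99% for HGPIN-Cancer minus Normal, and 86% and 96% for genotype within Dysplasia-LGPIN. The simulated noise was normal, independent between genes and of the same SD for a gene in every group. The changed genes also make the adjusted threshold easier to pass than where few genes change. A low count in the real data therefore does not show that changes of this size are absent.

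The text names, for each comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, leaving out clone names. Where none passed, the 4 smallest unadjusted p-values in each direction are named as values. Up to 4 members with the smallest p are named for each gene list described, and Fos and Jun wherever useful. In all, 33 gene lists were fixed before the data were examined, and those with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Camera was run again with an estimated correlation. The fry test, which asks whether the members move on balance in one direction and makes no comparison with other genes, was a further alternative.

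Alternatives planned before the data were examined were aligned array medians, all probe sets tested separately, array weights, a covariate for RNA integrity, a fit of only the groups compared, fits restricted by genotype, and leaving out each array in turn. The RNA integrity measure was the mean log2 difference between the 3' and 5' control probe sets of Actb and Gapdh. Alternatives added after seeing the data were a robust prior, only genes with above-median SD, the mean of the 18S rRNA control probe sets as a covariate, and leaving out 5 arrays high in seminal vesicle or nerve genes. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Coordinates are not printed because the table names no genome build.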

Results

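Gene expression was measured in prostate epithelium taken from normal wild-type glands and from lesions of mice mutant for Nkx3.1 and Pten, a homeobox gene of prostate epithelium and a phosphatase that opposes PI3-kinase signalling. The stages were Normal (4 arrays), Dysplasia-LGPIN (8), HGPIN-Cancer (6), AI-HGPIN (4) and AI-Cancer-MET (4), where PIN is prostatic intraepithelial neoplasia of low (LG) or high (HG) grade. AI is not spelled out in the labels; the study's topic makes androgen-independent disease the likely reading. The genotype codes were WT in the 4 Normal arrays, N in 4 Dysplasia-LGPIN arrays, and P, NP or TH in all the others. Dysplasia-LGPIN also held 1 P, 2 NP and 1 TH array, and HGPIN-Cancer 2 P, 3 NP and 1 TH. AI-HGPIN held 2 P and 2 NP arrays and AI-Cancer-MET 4 NP arrays. N and P presumably stand for the 2 mutant genes, and TH is left as labelled. Values are log2 ratios to the median of the Normal arrays.

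Among the 5 stages, 1551 of 12393 genes differed by the moderated F test. The first principal component held 36.1% of the variance and the second 11.4%. The first placed the Normal arrays at -39.5 ± 5.18 (SD, n = 4) and the N arrays of Dysplasia-LGPIN beside them at -29.6 ± 6.20 (n = 4). The P, NP and TH arrays of the same stage lay at 8.54 ± 4.87 (n = 4), next to HGPIN-Cancer at 15.9 ± 9.05 (n = 6), AI-HGPIN at 16.8 ± 6.67 (n = 4) and AI-Cancer-MET at 20.1 ± 5.27 (n = 4). The count of genes fell to 725 without the 5 arrays high in seminal vesicle or nerve genes, to 1015 without Normal replicate 2, and to 115 with 18S rRNA as a covariate. That covariate itself moved with stage, from -0.03 ± 0.78 (SD, n = 4) in Normal to -1.71 ± 0.35 (n = 6) in HGPIN-Cancer. The fall to 115 therefore cannot tell RNA composition from stage.

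**Figure D1:**
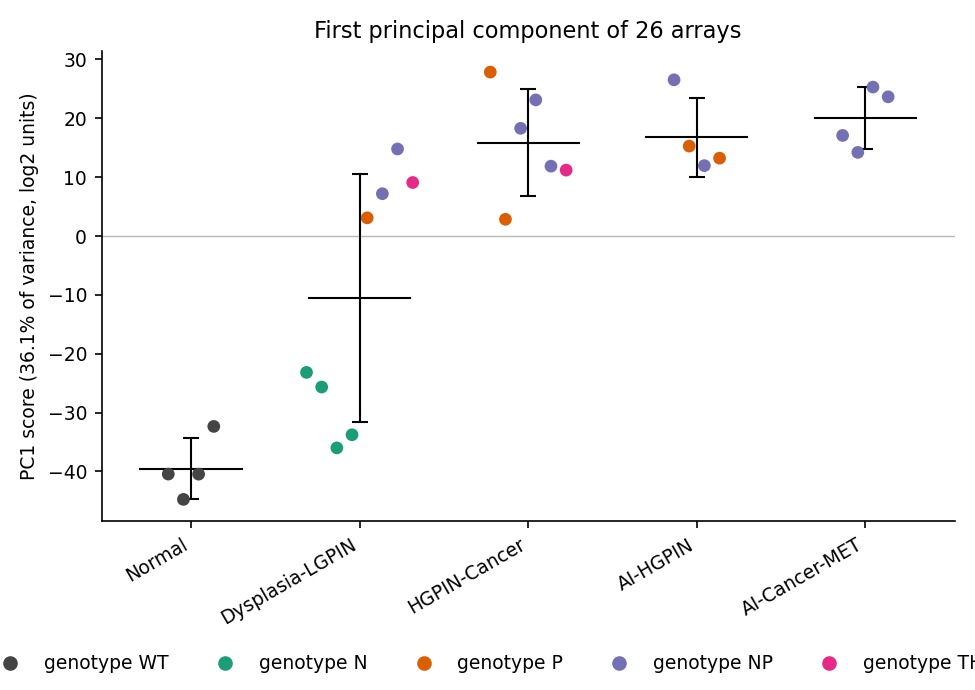
Score of each of the 26 arrays on the first principal component (vertical axis, log2 units) by stage (horizontal axis), coloured by genotype, with the mean and SD of each stage in black. The 4 N arrays of Dysplasia-LGPIN lie between -36.0 and -23.2 and the other 4 between 3.08 and 14.8.

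The step from normal epithelium to low-grade lesions was addressed by Dysplasia-LGPIN minus Normal. All Normal arrays were WT and no lesion array was. Stage and genotype therefore cannot be told apart in any difference from Normal, here or in HGPIN-Cancer. The largest rise was that of Nupr1, a stress-induced chromatin protein, at 5.39 ± 0.59 log2 units or 42.0-fold (SE, 8 against 4 arrays, adjusted p = 3.64e-06, higher in 8 of 8 arrays). It was followed by the metalloproteinase inhibitor Timp4 (3.27 ± 0.69), the annexin Anxa1 (3.22 ± 0.47), the cytochrome P450 Cyp2f2 (3.18 ± 0.47) and the sodium-potassium-chloride cotransporter Slc12a2 (3.15 ± 0.38). The carbonyl reductase Cbr2, Lrg1 and the anion exchanger Slc26a4 rose by 3.15 ± 0.44, 2.66 ± 0.44 and 2.63 ± 0.39. The largest fall was that of Pbsn, or probasin, an androgen-regulated secretory protein of the mouse prostate, at -4.54 ± 0.98 (adjusted p = 0.00867). Fcgbp (-3.62 ± 0.65), the gasdermin Gsdma (-3.55 ± 0.58), the complement protease C1ra (-3.32 ± 0.30), Fgl1 (-3.14 ± 0.21), the Rac regulator Chn2 (-2.88 ± 0.26), the ribonuclease Rnase1 (-2.85 ± 0.42) and Tmod4 (-2.84 ± 0.26) also fell. In all, 408 genes changed, 130 higher and 278 lower.

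Genes of the endoplasmic reticulum and secretory pathway were lower as a list in Dysplasia-LGPIN (camera adjusted p = 7.51e-10). Of 22 measured, 9 fell and 0 rose, and 12 fell when adjusted over the list alone. Creld2 fell by 2.07 ± 0.39, the stress sensor Atf6 by 1.26 ± 0.26, and Sel1l, which serves protein degradation there, by 0.92 ± 0.15. The interferon response list was higher (7.56e-10), with 3 of 27 genes past the threshold, both over all genes and adjusted over the list alone. They were Oasl2 (2.51 ± 0.63), Ifitm3 (2.07 ± 0.48) and Oas1a (1.53 ± 0.43). Markers of progenitor cells and PIN were higher too (1.12e-05), with Anxa1 the 1 of 14 past the threshold and 2 adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.408, 0.662 and 0.435. Macrophage and myeloid markers were higher beside them (0.00172, and 0.791 with an estimated correlation), with 0 of 15 past the threshold over all genes or adjusted over the list alone. The 18S rRNA control probe sets averaged -0.03 ± 0.78 (SD, n = 4) in Normal, -0.29 ± 0.56 (n = 4) in N arrays and -1.25 ± 0.74 (n = 4) in the P, NP and TH arrays.

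The N arrays and the other Dysplasia-LGPIN arrays shared some changes and differed in others. Fitted alone against Normal, N arrays differed in 157 genes, 74 higher and 83 lower, and the P, NP and TH arrays in 1262. Fgl1 was lower by -3.29 ± 0.22 in N arrays, and C1ra by -3.25 ± 0.37, while C1ra was lower by -3.38 ± 0.38 in the others. Nupr1 was higher by 3.94 ± 0.36 in N arrays and by 6.84 ± 0.22 in the others. In the P, NP and TH arrays 16 of 22 endoplasmic reticulum genes fell (18 adjusted over the list alone) and 9 of 14 progenitor and PIN-associated markers rose (10 adjusted over the list alone), and both lists had adjusted p = 0.0175 with an estimated correlation. In N arrays 1 of 22 and 1 of 14 did so (9 fell and 1 rose, and 1 rose and 1 fell, adjusted over the list alone), with camera adjusted p = 2.07e-05 for the endoplasmic reticulum list (0.759 with an estimated correlation) and 0.257 for the progenitor list. The progenitor mean was 0.38 ± 0.82 (SD, n = 4) in N arrays and 2.15 ± 0.37 (n = 4) in the others. The interferon mean was 0.25 ± 0.11 against 1.62 ± 0.62, with 0 of 27 genes past the threshold in N arrays (adjusted p = 0.068 for the list) and 13 in the others (20 adjusted over the list alone, 0.291 with an estimated correlation). The count of 408 also moved to 82 in a fit of only the 2 stages, where Timp4, Pbsn, Fcgbp and Gsdma missed the threshold (adjusted p from 0.0626 to 0.106), to 246 with 18S rRNA as a covariate, to 659 with all probe sets, to 266 without Normal replicate 1 and to 156 without Normal replicate 2. Pbsn missed it with only the N arrays (0.124), and Timp4 without Normal replicate 2 (0.0566) and without the 5 arrays high in seminal vesicle or nerve genes (0.299), and Normal replicate 4 held a Timp4 value of 3.39.

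**Figure D2:**
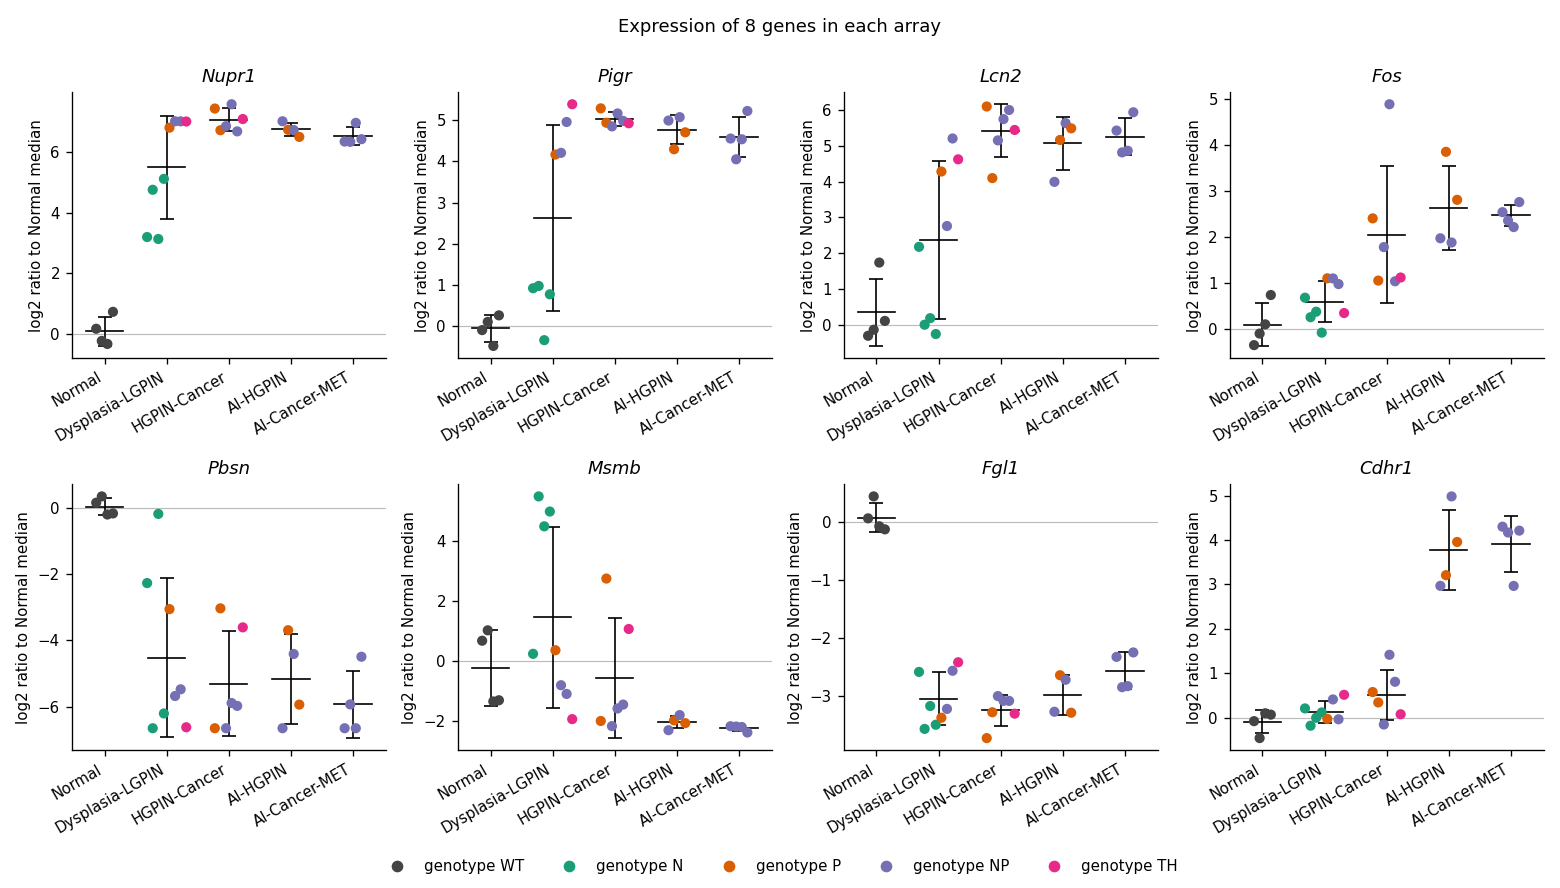
Log2 ratio to the Normal median (vertical axes) of 8 genes in each of the 26 arrays by stage (horizontal axes), coloured by genotype, with the mean and SD of each stage in black. Nupr1 and Fgl1 set all 8 Dysplasia-LGPIN arrays apart from Normal, Pigr sets apart the P, NP and TH arrays, and Cdhr1 averages 3.78 in AI-HGPIN and 3.91 in AI-Cancer-MET.

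Genotype within the single stage Dysplasia-LGPIN was compared as P, NP and TH together minus N. Wfdc18 was higher by 4.90 ± 0.45 log2 units or 29.8-fold (SE, 4 against 4 arrays, adjusted p = 3.89e-07), the trefoil factor Tff3 by 4.37 ± 0.64, the zinc transporter Slc39a4 by 4.22 ± 0.37 and Pigr, which carries immunoglobulin A across epithelia, by 4.10 ± 0.29. Basp1 (4.01 ± 0.33), Wfdc2 (3.99 ± 0.61), the siderophore-binding protein Lcn2 (3.68 ± 0.57) and the neutrophil chemokine Cxcl5 (3.68 ± 0.51) were also higher. The largest negative difference was that of Msmb, a secreted protein of the prostate, at -4.69 ± 1.00 (adjusted p = 0.00716). Defb1 (-3.36 ± 0.64), the glutathione peroxidase Gpx3 (-3.26 ± 0.48), H2-Q10 (-2.75 ± 0.69), Azgp1 (-2.63 ± 0.43), Pcp4 (-2.52 ± 0.60), Ramp1 (-2.46 ± 0.40) and the proton pump subunit Atp6v1c2 (-2.36 ± 0.24) followed. Each of these was on its side of the N mean in 4 of 4 arrays. Part of these differences lay in the N arrays. Against Normal, N arrays were higher for Msmb by 4.05 ± 1.03 (adjusted p = 0.0598), H2-Q10 by 3.08 ± 0.73 (0.0403) and Ramp1 by 2.44 ± 0.42 (0.00415), while the P, NP and TH arrays differed from Normal by -0.63 ± 0.84, 0.33 ± 0.33 and -0.02 ± 0.41. In all, 473 genes differed, 234 higher and 239 lower. The split was 169 higher and 73 lower in a fit of only these 8 arrays, and 150 higher and 483 lower without the 5 arrays high in seminal vesicle or nerve genes, which leaves 1 N array.

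Of 9 prostate secretory products, 3 were lower than in N arrays (6 adjusted over the list alone), Azgp1, Msmb and the peptidase Mme (-1.18 ± 0.22). Their mean was 0.48 ± 1.26 (SD, n = 4) in Normal, 1.41 ± 1.01 (n = 4) in N arrays and -0.93 ± 0.79 (n = 4) in the others. N arrays were above Normal for this list (0.00584, and 0.759 with an estimated correlation), with 2 of 9 up (4 up and 1 down adjusted over the list alone), while the others were not past the threshold against Normal (0.0804). The Normal mean rested on replicate 3, high in seminal vesicle genes, at 2.36 where the other Normal arrays lay between -0.24 and -0.01. The list shares Pate4 with the seminal vesicle genes, and without it the means were 0.28 ± 0.90, 1.34 ± 0.81 and -1.03 ± 0.88. Between the genotypes the list was lower with camera adjusted p = 1.63e-06, and 0.0481 with an estimated correlation (1.62e-06 and 0.045 without Pate4). Of 24 chemokines and inflammatory mediators, 8 rose (12 adjusted over the list alone), among them Cxcl15 (3.45 ± 0.34) and Cxcl2 (3.64 ± 0.45), with adjusted p = 6.33e-13 for the list and 0.0327 with an estimated correlation. Progenitor and PIN-associated markers were higher, with 7 of 14 past the threshold (9 adjusted over the list alone), led by Cd44 (3.31 ± 0.39). Their adjusted p was 2.11e-11, and 0.047 with an estimated correlation. Complement and acute phase genes were higher as well (4.1e-06, and 0.0481 with an estimated correlation), with 5 of 14 past the threshold (8 adjusted over the list alone), including Hp (1.70 ± 0.33) and Lbp (1.60 ± 0.31). Of 27 interferon response genes, 8 rose (19 adjusted over the list alone), with adjusted p = 2.21e-18 for the list and 0.109 with an estimated correlation. Of 22 ribosomal protein genes, 2 fell, Rps14 (-0.72 ± 0.16) and Rpl8 (-0.77 ± 0.21), and 8 fell adjusted over the list alone, with adjusted p = 5.03e-06 for the list and 0.233 with an estimated correlation.

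Macrophage and myeloid markers moved with genotype in the same arrays, with 3 of 15 past the threshold (5 adjusted over the list alone), adjusted p = 4e-09 for the list and 0.109 with an estimated correlation. Their mean was 0.75 ± 0.24 (SD, n = 4) in P, NP and TH arrays and 0.04 ± 0.17 (n = 4) in N arrays, and Cd14, Csf1r and Mpeg1 rose by 2.46 ± 0.33, 1.28 ± 0.27 and 1.27 ± 0.28. The 18S rRNA control probe sets averaged -1.25 ± 0.74 against -0.29 ± 0.56, and the 3' minus 5' difference 0.46 ± 0.09 against 0.00 ± 0.19. Seminal vesicle genes averaged 2.78 ± 3.22 in the N arrays and -0.05 ± 0.08 in the others. The count of 473 moved to 242 in a fit of only these 8 arrays, where Msmb and H2-Q10 missed the threshold (0.0716 and 0.262), to 313 without Dysplasia-LGPIN replicate 3 and to 291 without replicate 6. H2-Q10 missed it also with 18S rRNA as a covariate, with a difference about as large (-2.61), or without any 1 of Dysplasia-LGPIN replicates 2, 4, 6, 7 and 8 (adjusted p from 0.0543 to 0.0967), Pcp4 without any 1 of replicates 2, 3, 6 and 8 (from 0.0522 to 0.0621), and Gpx3 without the arrays high in seminal vesicle or nerve genes (0.0916), a setting that leaves 1 N array, replicate 2, and assumes that it varies like the other groups.

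High-grade lesions and cancer were set against normal tissue as HGPIN-Cancer minus Normal. Nupr1 was again the largest rise, at 6.94 ± 0.62 log2 units (SE, 6 against 4 arrays, adjusted p = 1.34e-07). Wfdc18 (5.38 ± 1.00), Pigr (5.09 ± 0.81), Lcn2 (5.06 ± 0.86), Wfdc2 (4.66 ± 0.92), the chemokine Cxcl15 (4.49 ± 0.72), Lrg1 (4.49 ± 0.47) and the interferon-induced Oasl2 (4.45 ± 0.66) followed. Pbsn was lower by -5.33 ± 1.04, Fcgbp by -4.65 ± 0.69, Gsdma by -4.29 ± 0.61, Rnase1 by -3.56 ± 0.45, the potassium pump Atp12a by -3.50 ± 0.46, the helix-loop-helix inhibitor Id3 by -3.47 ± 0.56, Fgl1 by -3.33 ± 0.22 and the proline dehydrogenase Prodh by -3.33 ± 0.46. Each of these 16 genes was on its side of the Normal mean in 6 of 6 arrays. Fos and Jun, the partners of the transcription factor AP-1, rose by 1.96 ± 0.53 (adjusted p = 0.0147) and 2.00 ± 0.58 (0.0216). In all, 1760 genes changed, 875 higher and 885 lower; with array medians aligned, 1031 were higher and 589 lower.

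Interferon response genes were the list with the smallest p (8.93e-17). Of 27 measured, 17 rose and 0 fell, and 24 rose adjusted over the list alone, for example Ifitm3 (3.15 ± 0.50) and Oas1a (2.51 ± 0.45). Among 24 chemokines and inflammatory mediators 12 rose and 1 fell (16 and 1 adjusted over the list alone), with adjusted p = 2.14e-09 and Cxcl2 higher by 4.02 ± 0.79. Glycolysis genes were higher (2.06e-06), with 9 of 15 up and 1 down (11 and 1 adjusted over the list alone). Hexokinase Hk2 rose by 2.60 ± 0.31 and the phosphofructokinase subunit Pfkl by 1.99 ± 0.35. Among luminal markers 6 of 12 rose and 1 fell (6 and 2 adjusted over the list alone, 0.00041). The keratins Krt19 (1.74 ± 0.30) and Krt8 (1.38 ± 0.25) rose, as did the cadherin Cdh1 (1.71 ± 0.30), while the peptidase Dpp4 fell by 1.03 ± 0.22. Cell cycle genes were higher (5.82e-06), with 10 of 29 up (13 up and 1 down adjusted over the list alone), including Pcna (0.97 ± 0.20), which clamps DNA polymerase, and Ccnb2 (0.64 ± 0.15). Progenitor and PIN-associated markers were higher (9.16e-08), with 7 of 14 up (10 adjusted over the list alone). Immediate early genes other than AP-1 were higher (8.33e-05), with 5 of 18 up, including Dusp1 (2.12 ± 0.46), and 7 up and 1 down adjusted over the list alone. Endoplasmic reticulum and secretory pathway genes were lower (6.7e-07), with 12 of 22 down and 0 up (14 and 1 adjusted over the list alone), Creld2 by 2.73 ± 0.41. The smallest adjusted p of any list with an estimated correlation was 0.184, so none of these list calls held there.

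Macrophage and myeloid markers rose beside these lists, 11 of 15 past the threshold (12 adjusted over the list alone), with adjusted p = 6.09e-10 for the list and 0.184 with an estimated correlation. Their mean was 1.12 ± 0.39 (SD, n = 6) in HGPIN-Cancer and -0.02 ± 0.28 (n = 4) in Normal. The 18S rRNA control probe sets averaged -1.71 ± 0.35 against -0.03 ± 0.78. The highest value in HGPIN-Cancer was -1.24 and the lowest in Normal -0.97, without overlap. A fit with this covariate therefore cannot separate RNA composition from stage. With 18S rRNA as a covariate the count of 1760 moved to 239, and Wfdc18 (3.55), Wfdc2 (3.23), Fos (1.95) and Jun (0.97) missed the threshold. It moved to 1171 without Normal replicate 2, where Jun missed it (0.0734), and to 1171 without the 5 arrays high in seminal vesicle or nerve genes, where Fos and Jun missed it with differences about as large (1.73 and 2.13, adjusted p = 0.146 and 0.078). Fos also missed it in a fit of only the 2 stages (0.0821), and Jun without HGPIN-Cancer replicate 4 (0.0548), which held the highest Fos value of its stage, 4.89.

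No gene passed the threshold for HGPIN-Cancer minus Dysplasia-LGPIN, the step from low to high grade. The smallest adjusted p in limma was 0.119, and 2071 genes had an unadjusted p under 0.05 where 620 would by chance. The genes with the smallest p were Pcna (0.88 ± 0.17, SE, 6 against 8 arrays), the acute phase gene Saa3 (2.02 ± 0.40), Krt19 (1.22 ± 0.25) and Plekha1 (0.76 ± 0.16) on the higher side. On the lower side they were the ceramide synthase Cers4 (-0.60 ± 0.14), the mast cell protease Cpa3 (-0.37 ± 0.09), Plppr2 (-0.22 ± 0.05) and Cdip1 (-0.28 ± 0.07). Fos differed by 1.46 ± 0.44 (adjusted p = 0.139) and Jun by 1.27 ± 0.48 (0.203), and Fos by 0.89 ± 0.30 without HGPIN-Cancer replicate 4 (0.319). Interferon response genes were higher as a list (3.79e-11, and 0.224 with an estimated correlation), with 0 of 27 past the threshold and 12 adjusted over the list alone. Macrophage markers were too (2.29e-10, and 0.117 with an estimated correlation), with 0 of 15 and 10 adjusted over the list alone. Glycolysis genes (1.58e-08, and 0.105 with an estimated correlation) had 0 of 15 and 9 adjusted over the list alone, with Tpi1 at 1.30 ± 0.31 and Pkm at 1.27 ± 0.29.

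Set against the P, NP and TH arrays of Dysplasia-LGPIN alone, HGPIN-Cancer again gave 0 genes, with 719 at an unadjusted p under 0.05 and a smallest adjusted p of 0.816. Pcna differed there by 0.78 ± 0.18, Saa3 by 1.44 ± 0.46, Krt19 by 0.86 ± 0.27 and Plekha1 by 0.45 ± 0.16. The list differences were smaller too. The mean over the interferon response genes was 0.19 in place of 0.87 (camera adjusted p = 0.0441, and 0.659 with an estimated correlation), over macrophage markers 0.37 in place of 0.73 (0.000271, and 0.392) and over glycolysis genes 0.39 in place of 0.69 (0.000271, and 0.341), with 0 genes of each past the threshold adjusted over the list alone. The count of 0 against all 8 Dysplasia-LGPIN arrays depended on single arrays. It moved to 215, of which 188 were higher, without Dysplasia-LGPIN replicate 7, an NP array, to 25 without HGPIN-Cancer replicate 2, and to 1, Pcna, without HGPIN-Cancer replicate 3. With array weights it was 2.

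For AI-HGPIN minus HGPIN-Cancer, 2 genes passed the threshold, both higher. By its name HGPIN-Cancer also holds cancer and AI-HGPIN does not, so the AI label is partly mixed with grade here. Cdhr1, a cadherin-related membrane protein, rose by 3.27 ± 0.32 log2 units or 9.61-fold (SE, 4 against 6 arrays, adjusted p = 2.55e-06). Cxcl13, a chemokine that attracts B cells, rose by 2.38 ± 0.23 or 5.19-fold (2.55e-06), through the probe set used, while all its probe sets ranged from 0.48 to 2.38. Both were higher in 4 of 4 arrays and passed under every alternative run. Heat shock proteins were lower as a list (1.62e-05, and 0.83 with an estimated correlation), with 0 of 13 past the threshold and 1 adjusted over the list alone. Oxidative phosphorylation genes were lower (1.62e-05, and 0.899 with an estimated correlation), with 0 of 33 past it over all genes or adjusted over the list alone. Lymphocyte markers were higher (0.00764, and 0.899 with an estimated correlation), with 0 of 16 past it over all genes or adjusted over the list alone, and Jchain at 1.63 ± 0.61. The heat shock mean was 0.56 ± 0.48 (SD, n = 6) in HGPIN-Cancer, with 1.44 in replicate 4. It was -0.06 ± 0.20 (n = 4) in AI-HGPIN and -0.05 ± 0.10 (n = 4) in Normal, so HGPIN-Cancer was the stage that stood apart. Prostate secretory products did not stand apart (adjusted p = 0.261), nor did androgen-regulated genes outside that list (0.539). Fos differed by 0.58 ± 0.53, by 1.15 ± 0.35 without HGPIN-Cancer replicate 4 and by 0.17 ± 0.55 without AI-HGPIN replicate 2. Jun differed by -0.10 ± 0.58, and leaving out 1 array moved it between -0.42 (without AI-HGPIN replicate 1) and 0.22 (without HGPIN-Cancer replicate 4). The count of 2 was 36 with array weights, 9 in a fit of only these stages, 6 with genotype as a covariate, 4 with all probe sets and 4 without HGPIN-Cancer replicate 3.

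Within the AI arm, AI-Cancer-MET minus AI-HGPIN gave 1 gene. All 4 AI-Cancer-MET arrays were NP, while AI-HGPIN held 2 NP and 2 P arrays, so grade is partly mixed with genotype here. Gp2, a membrane glycoprotein best known from pancreatic granules, was higher by 0.70 ± 0.10 log2 units or 1.62-fold (SE, 4 against 4 arrays, adjusted p = 0.00869). Only 331 genes had an unadjusted p under 0.05, fewer than the 620 expected by chance. Fibroblast and matrix genes were lower as a list (0.000149), with 0 of 24 past the threshold over all genes or adjusted over the list alone, and Lum at -0.51 ± 0.19. Macrophage markers were higher (0.00502), with 0 of 15 past it either way. Both lists had adjusted p = 0.992 with an estimated correlation. The fibroblast and matrix mean was 0.08 ± 0.31 (SD, n = 4) in AI-HGPIN and -0.16 ± 0.12 (n = 4) in AI-Cancer-MET. In AI-HGPIN it was 0.51 in replicate 2 and between -0.18 and 0.11 in the other arrays, so the difference leaned on that array. Gp2 missed the threshold without any 1 of AI-HGPIN replicates 1 and 4 and AI-Cancer-MET replicates 2 and 3, in a fit of only these stages, with only genotype NP, with only the more variable genes and without the arrays high in seminal vesicle or nerve genes. Its difference there stayed about as large, from 0.63 to 0.74, while its adjusted p ran from 0.062 to 0.756. Without AI-Cancer-MET replicate 4 the count was 2.

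**Figure D3:**
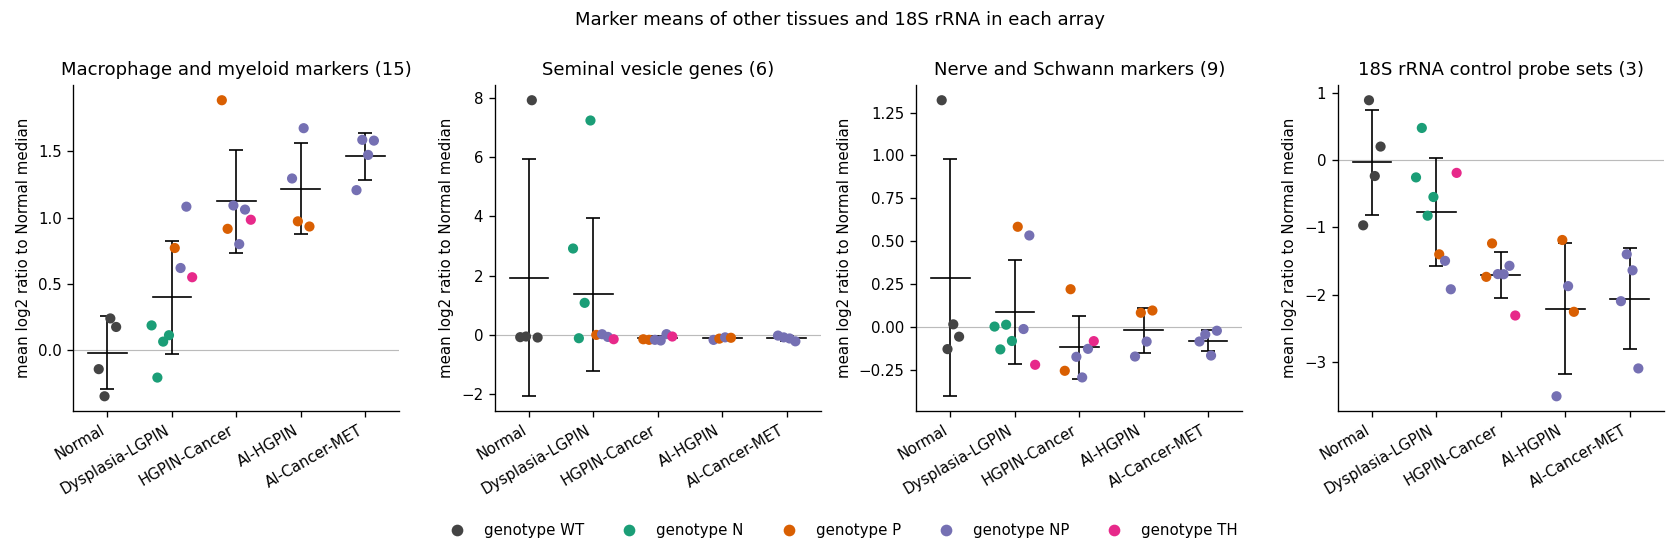
Mean log2 ratio to the Normal median (vertical axes) of markers of other tissues and of the 18S rRNA control probe sets in each of the 26 arrays by stage (horizontal axes), coloured by genotype, with the mean and SD of each stage in black. Seminal vesicle genes reach 7.92 in 1 Normal array and 7.23 in 1 Dysplasia-LGPIN array, nerve markers reach 1.32 in 1 Normal array, and macrophage markers average 1.46 in AI-Cancer-MET.

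Markers of other tissues stood apart in a few arrays. The mean of 6 seminal vesicle secretory genes was 7.92 in Normal replicate 3, 7.23 in Dysplasia-LGPIN replicate 4, 2.92 in replicate 1 and 1.08 in replicate 3. Nerve and Schwann cell markers averaged 1.32 in Normal replicate 1 and lay between -0.13 and 0.02 in the other Normal arrays. Among the lesions they averaged 0.58 and 0.53 in Dysplasia-LGPIN replicates 5 and 7 and 0.22 in HGPIN-Cancer replicate 2. Lymphocyte markers averaged 0.19 ± 0.14 (SD, n = 6) in HGPIN-Cancer, 0.40 ± 0.17 (n = 4) in AI-HGPIN and 0.40 ± 0.08 (n = 4) in AI-Cancer-MET. Smooth muscle markers averaged 0.12 ± 0.39 (n = 4) in Normal and -0.20 ± 0.17 (n = 6) in HGPIN-Cancer, where the list was lower than in Normal (0.0065, and 0.312 with an estimated correlation) with 4 of 15 down and, adjusted over the list alone, 8 down and 1 up. That call was lost without the 5 arrays (0.444).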

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

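The tests on seminal vesicle genes, nerve genes and luminal markers and the tests with macrophage markers or 18S rRNA as a covariate were chosen only after the data had been seen. Single arrays far from the others of their stage were sought with Dixon's test at its 95% level in 315 groups of values. It found 29, where chance flags about 1 in 20 groups, or 15.8.

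Among genes, Normal replicate 4 stood apart for Timp4 (3.39), Cbr2 (1.93), Saa3 (0.572) and Gp2 (0.145). HGPIN-Cancer replicate 2 stood apart for Fcgbp (-3.07), Chn2 (-2.57), Saa3 (1.23), Wfdc18 (3.38) and Pcp4 (-0.417), HGPIN-Cancer replicate 4 for Fos (4.89) and HGPIN-Cancer replicate 1 for Tff3 (0.262). Dysplasia-LGPIN replicate 3 did so for Chn2 (-1.57). In the AI stages the arrays were AI-HGPIN replicate 4 for Timp4 (1.73), replicate 3 for Cxcl15 (3.86) and replicate 1 for Cxcl5 (4.58). AI-Cancer-MET replicate 3 stood apart for Nupr1 (6.94), Cpa3 (-0.205) and Cdhr1 (2.97), replicate 2 for Plekha1 (0.25) and replicate 4 for Msmb (-2.40).

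Among means of marker lists, macrophage markers were high in HGPIN-Cancer replicate 1 (1.89), and smooth muscle markers in Dysplasia-LGPIN replicate 2 (0.529) and AI-HGPIN replicate 2 (0.0496). Nerve markers were high in Normal replicate 1 (1.32), and neuroendocrine markers in HGPIN-Cancer replicate 2 (0.534) and AI-HGPIN replicate 4 (0.145). Seminal vesicle genes were high in Normal replicate 3 (7.92) and Dysplasia-LGPIN replicate 4 (7.23), and prostate secretory products in Normal replicate 3 (2.36).

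Differences between groups were tested directly for 2 questions. The first was whether the Dysplasia-LGPIN minus Normal difference depends on genotype. The same Normal arrays, all WT, serve both genotype groups and drop out. This test is therefore the comparison of P, NP and TH with N arrays given above, with its 473 genes, and not a separate result. AI-Cancer-MET minus AI-HGPIN was set against HGPIN-Cancer minus Dysplasia-LGPIN. These are different steps of grade, and the genotypes are unevenly spread in both. The 1 gene that differed was Gp2 (limma adjusted p = 0.0259). It averaged 0.70 ± 0.24 (SD, n = 4) in AI-Cancer-MET, 0.00 ± 0.09 (n = 4) in AI-HGPIN, 0.02 ± 0.09 (n = 6) in HGPIN-Cancer and 0.14 ± 0.16 (n = 8) in Dysplasia-LGPIN. Outside the named genes, 239 of 2246 probe sets with several gene names or none differed between HGPIN-Cancer and Normal, 116 higher and 123 lower.

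The same arrays were also split into other groups of the same sizes. Such splits can keep part of the real grouping. Where the real groups differ, mixing them also widens the spread within groups, so low counts in other splits are partly built in. For genotype within Dysplasia-LGPIN the real grouping, with 473 genes, was the highest of 35 possible splits, the next giving 3. It was also the highest of 100 for HGPIN-Cancer minus Normal (1760 against 142) and for the 5 stages (1551 against 21). The split that gave 142 kept all Normal arrays together. For Dysplasia-LGPIN minus Normal 2 of 100 splits, the real one included, gave at least 408. The highest gave 568 and kept all P, NP and TH arrays together. For AI-HGPIN minus HGPIN-Cancer 2 of 100, the real one included, gave at least 2 genes. For AI-Cancer-MET minus AI-HGPIN 8 of 35, the real one included, gave at least 1 and the highest gave 38, so that count is no more than other groupings of these arrays give. For HGPIN-Cancer minus Dysplasia-LGPIN the real count was 0, which every split reaches, so the splits decide nothing there. The highest gave 20 and kept all N arrays together.

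The split of Dysplasia-LGPIN by genotype was weighed against RNA from leukocytes and against RNA quality. The macrophage marker mean was added as a covariate for the 231 genes that were higher in P, NP and TH arrays and are not themselves macrophage markers. They kept a median share of 0.916 of their difference. The quartiles of the share were 0.79 and 1.03. Only 62 of them stayed past the threshold, as their median difference went from 1.27 to 1.17 and their median SE from 0.284 to 0.356. The marker mean lay between -0.21 and 0.19 in N arrays and between 0.55 and 1.08 in the others, without overlap. The slope of the covariate therefore came from the spread within groups, and this test cannot separate leukocyte RNA from genotype. The 12 luminal markers had a median difference of 0.59 (SD over markers 0.873, range -1.553 to 1.524), against -0.78 for the genes called lower. Some N arrays were high in seminal vesicle genes, and the luminal list was also higher in HGPIN-Cancer than in Normal. The median therefore cannot decide whether epithelial RNA was diluted. With 18S rRNA as a covariate the called genes kept a median share of 0.981 and 295 of 473 stayed past the threshold, and with the 3' minus 5' difference the values were 1.04 and 360. The median SE went from 0.229 to 0.247 and to 0.249. The 3' minus 5' difference lay between -0.22 and 0.25 in N arrays and between 0.40 and 0.59 in the others, without overlap. Its test therefore has the same limit as that with macrophage markers and cannot separate RNA integrity from genotype. A part played by leukocyte RNA, 18S rRNA or RNA integrity is not excluded. Genotype is the explanation the design gives, and it was not tested separately from these measures. Lesions of 1 stage name may also differ in severity or age between genotypes, which was not tested.

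Seminal vesicle genes in Normal replicate 3 and Dysplasia-LGPIN replicate 4 were weighed next. If seminal vesicle RNA of one composition had entered both, the 6 genes would stand in one ratio, and the SD over genes of the difference between the arrays was 0.497. This fits such RNA, from neighbouring tissue or secretion, as a candidate explanation. A smaller share of the same RNA as in Normal replicate 3 was then asked of Dysplasia-LGPIN replicates 1 and 3. Around the values that the median gene's share gives, the SD over genes was 0.50 in replicate 4 and 1.95 in replicate 1. At that share Svs2 would stand at 1.63 and Pate4 at 3.47 in replicate 1, and they stood at 0.04 and 0.37 beside 6.76 for Svs4, which argues against RNA of that composition there. In replicate 3 the SD was 1.08 with values down to 0.26 predicted, so close to the other arrays that such a share and another source cannot be told apart. No biological explanation was tested.

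Nerve genes in Normal replicate 1 were the third pattern. Of 9 nerve and Schwann cell markers 5 were highest of all 26 arrays there, against 0.346 by chance, and so were 8 of 14 neuroendocrine markers, against 0.538. The markers highest there were Nefl (4.49), Pmp22 (3.25), Gap43 (2.05), Nefm (1.24) and Mbp (0.91). S100b (-0.02), Sox10 (0.03), Gfap (-0.12) and Prnp (0.08) were not raised. The count in part restates the high mean that led to it, and the markers go both ways, so nerve tissue in the captured area and other sources of these transcripts cannot be told apart. No biological explanation was tested.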

How the results depend on the processing

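The Fos and Jun values between lesion stages without single arrays, the robust prior, the filter on variable genes, the 18S rRNA covariate and the removal of 5 arrays or of Pate4 from a list were chosen only after seeing the data, as was the comparison of both AI stages with HGPIN-Cancer. Counts not named here stayed within 1.5 times, with array medians aligned, the 3' minus 5' covariate and the robust prior among the settings that moved none. With array medians aligned, HGPIN-Cancer minus Normal gave 1031 higher and 589 lower genes instead of 875 and 885.

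Dysplasia-LGPIN minus Normal (408) moved to 659 with all probe sets, 82 with only the groups compared, 246 with the 18S rRNA covariate, 157 with only genotype N and 1262 with only P, NP and TH. Leaving out 1 array at a time gave 156 to 590. HGPIN-Cancer minus Dysplasia-LGPIN (0) moved to 2 with array weights, and 0 to 215 leaving out 1 array. AI-HGPIN minus HGPIN-Cancer (2) moved to 4 with all probe sets, 36 with array weights, 9 with only the groups compared and 6 with the genotype covariate, and 2 to 4 leaving out 1 array. AI-Cancer-MET minus AI-HGPIN (1) fell to 0 with only the groups compared, 0 with more variable genes only, 0 without the arrays high in nerve or seminal vesicle genes and 0 with only genotype NP, and 0 to 2 leaving out 1 array. HGPIN-Cancer minus Normal (1760) moved to 239 with the 18S rRNA covariate and 1171 without the 5 arrays, and 1171 to 1788 leaving out 1 array. Genotype within Dysplasia-LGPIN (473) moved to 242 with only the groups compared, and 291 to 593 leaving out 1 array. The 5 stages (1551) moved to 115 with the 18S rRNA covariate and 725 without the 5 arrays, and 1015 to 1723 leaving out 1 array. Both AI stages minus HGPIN-Cancer (20) ranged from 4 to 70 leaving out 1 array. Fits of fewer arrays or groups hold less information by construction, and a fit of only the groups compared also takes the spread from those groups alone. Less information does not account for every move of that fit. Its count rose from 2 to 9 for AI-HGPIN minus HGPIN-Cancer and was 1679 against 1760 for HGPIN-Cancer minus Normal. The causes of the moves were not tested.

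Seminal vesicle genes, lower in P, NP and TH than in N arrays, turned direction without the 5 arrays (adjusted p = 0.623). The loss of the excess in N arrays is fixed by this choice, since 4 of the 5 were left out for these same genes. The setting leaves 1 N array, replicate 2, which is assumed to vary like the other groups, and 2 Normal arrays, so this direction rests on 1 sample. Among the list calls of the 6 planned comparisons, an estimated correlation kept 4 and lost 60, and fry kept 34 and lost 30. Leaving out 1 array kept 611 named-gene results, lost 16 and gained 13. No named gene past the threshold turned direction. Between lesion stages, neither Fos nor Jun passed it. Without single arrays, Jun turned direction in AI-HGPIN minus HGPIN-Cancer, and both genes did so in AI-Cancer-MET minus AI-HGPIN. Fos kept its direction in AI-HGPIN minus HGPIN-Cancer, and both genes kept theirs in HGPIN-Cancer minus Dysplasia-LGPIN.

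Pseudocounts, quantile normalization, a filter on mean level and an intensity trend were planned and not run, because ratios hold no levels. Dividing by the Normal median also narrows the spread over probe sets within a Normal array, though not the spread of a gene between arrays. As ratios hold no levels, signal over background is unknown, and how far it limits weakly expressed genes could not be assessed. No paired analysis was possible because the numbers in the titles run on within each genotype and no label says that 2 arrays share a mouse, a day or a batch.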

Other observations

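The comparison below was chosen only after the data had been seen. Grade is not matched in it, as the labels do not say which HGPIN-Cancer arrays are HGPIN and which are cancer. With AI-HGPIN and AI-Cancer-MET pooled (8 arrays) and set against HGPIN-Cancer (6 arrays), 20 genes passed the threshold in limma, 11 higher and 9 lower, each on its side of the HGPIN-Cancer mean in 8 of 8 AI arrays. The chemokine Cxcl13 was higher by 2.85 ± 0.20 log2 units or 7.20-fold (SE, adjusted p = 3.11e-09) and Cdhr1 by 3.33 ± 0.27 or 10.1-fold (4.5e-08). The carbonic anhydrase Car12 (2.10 ± 0.37), the lipoprotein lipase Lpl (1.47 ± 0.31), the water channel Aqp4 (1.22 ± 0.24), the GABA receptor subunit Gabrp (0.88 ± 0.18) and the metalloproteinase Mmp9 (0.71 ± 0.15) were higher as well. Dnase1l2 (-1.09 ± 0.22), the sulfatase Sulf2 (-0.89 ± 0.18), the mitochondrial ribosomal gene Mrps24 (-0.80 ± 0.16), the kinase Mapk13 (-0.80 ± 0.17) and the receptor kinase Tyro3 (-0.76 ± 0.12) were lower. An unadjusted p under 0.05 was found for 1135 genes.

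Beside these genes, lymphocyte markers were higher as a list in the AI arrays (camera adjusted p = 0.000791, and 0.783 with an estimated correlation), with 0 of 16 past the threshold. Macrophage and myeloid markers were higher too (0.0216, and 0.946 with an estimated correlation), with 0 of 15 past it. The list with the smallest p, heat shock proteins, was lower (4.24e-05, and 0.783 with an estimated correlation), with 0 of 13 past it. Cell cycle genes (0.000791) and oxidative phosphorylation genes (0.00124) were lower, each 0.946 with an estimated correlation, with 0 of 29 and 0 of 33 past it. The heat shock mean was raised in HGPIN-Cancer (0.56 ± 0.48, SD, n = 6). In AI-HGPIN (-0.06 ± 0.20, n = 4) and AI-Cancer-MET (-0.05 ± 0.38, n = 4) it lay near that of Normal (-0.05 ± 0.10, n = 4). In 100 random regroupings of the 14 arrays, only the real one reached 20 genes, the next giving 8. The count depended on single arrays, from 4 without HGPIN-Cancer replicate 4 to 70 without HGPIN-Cancer replicate 3.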
